A study of Rattus norvegicus with 6 samples.

How the data were processed

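The series holds 6 Affymetrix arrays of total RNA from cultured rat olfactory ensheathing cells, 3 of type U34A (8799 probe sets) and 3 of type RAE2.0 (31099 probe sets), with 1 array per population on each. Per the labels, OEC Ep cells were grown for 1 week (less than 3 population doublings) and OEC Lp cells for over 50 doublings, both from Wistar rats at postnatal day 21, while the donors of TEG3 were 60 days old. All were kept in DMEM with 3% serum, 20 µg/ml pituitary extract and 2 µM forskolin, and a purity over 90% by immunocytochemistry is stated for OEC Ep and OEC Lp. The design text says that 2 RNA pools, each of 3 cultures, were made per population with TRIZOL and names U34A arrays alone. Which pool went on which array, and whether the RAE2.0 arrays carried the same RNA, is not stated.

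The deposited values are signal intensities on a linear scale that the authors obtained with MAS5, per the labels, and the design text names Microarray Suite version 5.0 and a filter on inaccurately represented probe sets whose setting is not given. The intensity tables hold whole numbers for every probe set of the array without detection calls, and the mean after trimming 2% of probe sets at each end was near 1000 on all arrays. Each array was scaled to the same 2% trimmed mean within its type. Signals below the 40th percentile of the type (128.4 on U34A, 168 on RAE2.0) were set to that floor, control probe sets (59 and 57) were left out, and probe sets had to exceed the floor on at least 1 of 3 arrays, which 6360 and 22185 did. Probe sets were joined to genes where the platform annotation gave a single symbol (7006 and 20826); those with several (308 and 436) or none (1426 and 9780) were left out of the gene analysis. A gene's value was the mean log2 signal of its probe sets. This gave 3726 genes on U34A and 11542 on RAE2.0, 3131 of them on both. A fold against a population at the floor is a lower bound and is written "at least", and the log2 fold beside it is a bound in the same way where the array types have the same sign. For genes on both types the bound applies to the mean of the log2 ratios over the types, and the ratio on 1 type can be smaller. The reference table of genes was used for symbols alone, and no coordinates were used.

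Genes on both types were fitted with limma 3.58.1 in R 4.3.3 with a term for population and a term for array type, which is also the replicate number and therefore the replicate block. Moderated p-values were adjusted by the Benjamini-Hochberg method at 0.05. The residual is the disagreement of the array types on the population difference, with 2 residual and 3.56 prior degrees of freedom. The 5 contrasts were OEC Lp against OEC Ep, TEG3 against OEC Ep, TEG3 against OEC Lp, OEC Lp against the mean of the others and OEC Ep against the mean of the others; in the last 2 a gene was called where both pairwise differences also had the same sign on both types. Genes on RAE2.0 alone (8411) have 1 array per population and are given as values with no test. Single genes were tested with limma alone.

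In all, 24 gene lists were written from textbook knowledge, covering OEC and Schwann cell, microglia and macrophage, neuron, oligodendrocyte, astrocyte, fibroblast and meningeal, endothelial and contractile markers, matrix components, matrix proteases, protease inhibitors, integrins and adhesion, growth factors, axon guidance, cytokines and complement, interferon and MHC, DNA replication, mitosis, p53 targets, senescence, cholesterol synthesis, glycolysis and hypoxia, ribosomal proteins and antioxidant genes. The 23 lists with at least 5 genes on both types were tested with camera with a preset correlation between genes of 0.01, adjusted over 115 tests, and with an estimated correlation and fry as alternatives. Their medians on each type were set against 10000 random lists of similar signal. Counts of members are given adjusted over all genes and adjusted over the list alone.

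Genes named in the text were chosen by a rule: the 8 largest changes in each direction per pairwise comparison among called genes with the same sign on both types, up to 4 members of each list with the lowest p, the 4 highest and 4 lowest ratios of genes on RAE2.0 only, and the 6 largest in each direction of the combined contrasts. Always given where measured were Mmp2, Mmp9, Mmp14, Timp1, Timp2, Timp3, Plat, Plau, F2r, Bdnf, Gdnf, Ngfr, S100b, Gfap, Sox10, Npy, Fn1, Vim, Thy1 and Cdkn2a. Other genes of that part of the rule were not analysed here, and predicted or unnamed genes were skipped in naming. Of list members the text gives examples from this choice. The comparisons, lists, naming rule and alternatives were set before the data were examined.

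The procedure was tested on simulated data for OEC Lp against OEC Ep, with 200 genes changed in each of 20 runs. It recovered 2.6% of genes changed 2-fold, 49.8% at 4-fold, 77.7% at 8-fold and 81.4% at 16-fold, and 1.3% of calls were false. The simulated spread was drawn independently for each probe set, and no other genes were changed. Spread shared by many genes was therefore absent, unlike in the data, where the correlation estimated for interferon and MHC genes was 0.645. The share of false calls is not an error rate for these data. Alternatives were the values as deposited, quantile normalization, median scaling, no floor, a floor at the 60th percentile, no filter, genes above the floor on all arrays, the brightest probe set per gene, the 4 arrays of the populations compared, a trend in the prior variance, no replicate block, each array left out in turn and a 4-fold threshold for probe sets. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.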

Results

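Total RNA of 3 populations of cultured rat olfactory ensheathing cells (OECs), the glia that surround olfactory axons, was measured on 6 Affymetrix arrays. OEC Ep was a short-term primary culture from the olfactory nerve layer, with less than 3 population doublings. OEC Lp was a primary culture of the same origin that had gone through more than 50 doublings. TEG3 was a clonal line made from OECs with the large T antigen of the SV40 virus, a protein that binds the retinoblastoma protein. Each population was hybridised to 1 U34A array and 1 RAE2.0 array, so a fold from both types rests on 2 arrays per population and a fold from RAE2.0 only on 1, and these numbers limit the precision. The arrays of a type had similar shares of probe sets above the floor, 59.2 to 61.6% on U34A and 59.1 to 61.8% on RAE2.0. The ratio of GAPDH signal at the 3' end to that at the 5' end, a sign of RNA quality, was 1.96 in OEC Ep, 1.52 in OEC Lp and 1.54 in TEG3 on U34A. On RAE2.0 it was 1.02, 0.981 and 1.02 in the same order.

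The first question was whether the array types show the same population differences, since their probes differ. Sox10, a transcription factor of glia from the neural crest, had signals of 2904, 128 and 201 in OEC Ep, OEC Lp and TEG3 on U34A and of 5743, 168 and 233 on RAE2.0, where 128 and 168 are the floors. Apoe, which codes for a lipid carrier, had signals of 20260 in OEC Ep and 292 in TEG3 on U34A and of 22930 and 299 on RAE2.0. F2r, the thrombin receptor, differed between the types: its signal in OEC Lp was at the floor on U34A but 4880 on RAE2.0. Such differences were common. The types gave the same direction for 65.1% of genes in OEC Lp against OEC Ep, with a ratio of 0 counted as lower. The share was 68.5% in TEG3 against OEC Ep and 61.2% in TEG3 against OEC Lp. Over the 3131 genes on both types, the log2 ratios correlated with a Pearson r of 0.63 for OEC Lp against OEC Ep, 0.678 for TEG3 against OEC Ep and 0.516 for TEG3 against OEC Lp. The Spearman rho was 0.446, 0.545 and 0.367. These values are across genes, which are not independent replicates. Ratios of different comparisons set against each other gave r from -0.239 to 0.503. Of the 6 ways to match the populations of the types, the labels' own gave a mean r of 0.608 and 366 calls by limma over the 3 comparisons, and the highest other, with OEC Lp and TEG3 exchanged, gave 0.141 and 63. At least 2-fold differences were seen for 1490, 1611 and 1308 probe sets on U34A and for 4685, 4786 and 4034 on RAE2.0 in the 3 comparisons, with no replicate check within a type.

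**Figure D1:**
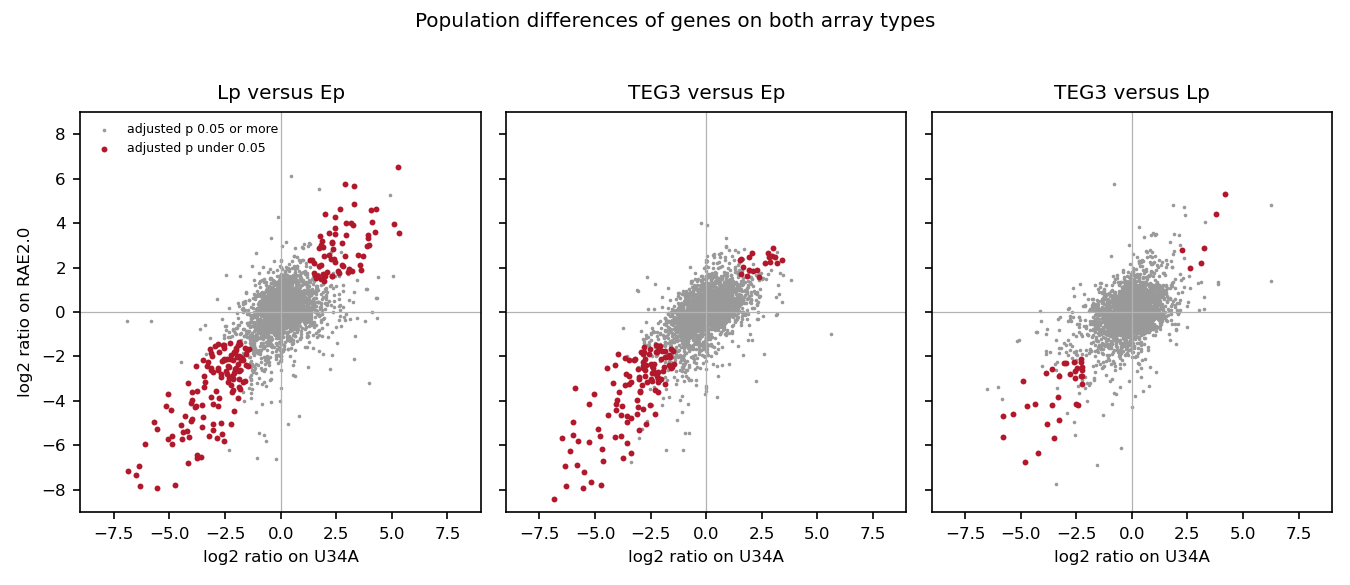
Log2 ratios of 3131 genes on U34A (x axis) and RAE2.0 (y axis) in the 3 pairwise comparisons, with genes of limma adjusted p under 0.05 in red. All 192, 136 and 38 red genes lie in the quadrants where both array types have the same sign, which is built into the test, since its residual is the disagreement of the types.

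OEC Lp was compared with OEC Ep to ask how cells kept in culture for more than 50 doublings differ from short-term cultures of the same tissue in the same medium. S100b, a calcium-binding protein of glia, fell at least 107-fold (log2 fold -6.74 ± 0.645 SE, limma adjusted p = 0.00879). Sox10 fell at least 27.8-fold (log2 fold -4.80 ± 0.335, adjusted p = 0.00469). Npy, a neuropeptide made by OECs, fell at least 22.6-fold (adjusted p = 0.00867). The largest falls were those of Calcb, a calcitonin gene-related peptide, with at least 134-fold (log2 fold -7.06 ± 0.466, adjusted p = 0.00469), Postn, the matrix protein periostin, with at least 129-fold, and Lyz2, the lysozyme of macrophages, with at least 121-fold. Nefm, a neurofilament subunit, Scn7a, a sodium channel of glia, and Tubb2b, a beta tubulin, fell at least 99.1-fold, 77.8-fold and 64.9-fold, and Cd200, a surface glycoprotein, fell 44.7-fold. In the other direction, Tnnt2, the cardiac troponin T, rose at least 59.3-fold (log2 fold 5.89 ± 0.502, adjusted p = 0.00676). The gap junction protein Gjb2 rose 22.9-fold (adjusted p = 0.0162), and Igfbp6, which binds insulin-like growth factors, at least 22.0-fold. Omd, an osteoglycin-like proteoglycan, Clu, the chaperone clusterin, Tspan8, a tetraspanin, Masp1, a complement protease, and Cav1, the coat protein of caveolae, rose at least 22.6-fold, 21.5-fold, 20.1-fold, 19.9-fold and 16.9-fold.

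Markers of OECs and Schwann cells were the list with the lowest camera adjusted p in this comparison, 6.74e-14 (adjusted p = 0.372 with an estimated correlation). Of its 18 genes on both types 12 fell and 0 rose, 14 fell when adjusted over the list alone, and the median log2 fold was -3.60. Besides Sox10, S100b and Npy, the receptors and adhesion molecules Gfra1 (at least 14.5-fold) and L1cam (at least 16.7-fold) fell. Ngfr, the low-affinity neurotrophin receptor used to identify OECs, had a log2 fold of -4.26 ± 1.06 that missed the threshold (adjusted p = 0.0912) and is a lower bound in size. On U34A it had -2.31, where its signal in OEC Lp was still 2569, and on RAE2.0 -6.22, where it was at the floor. The intermediate filament Vim had a log2 fold of -0.25 (adjusted p = 0.714). Gfap, the intermediate filament of astrocytes and OECs, was measured on RAE2.0 only, where its signal was 3236 in OEC Ep and at the floor in OEC Lp. Microglia and macrophage markers were lower too: of 12 genes 6 fell over all genes and 11 adjusted over the list alone, with a median of -2.48 and a camera adjusted p of 6.98e-11 (adjusted p = 0.372 with an estimated correlation). Examples are Aif1 (at least 8.93-fold), C1qb (at least 12.8-fold) and the cathepsin Ctss (at least 20.9-fold). On RAE2.0 alone, 21 of 23 such markers were at least 2-fold lower in OEC Lp. The GAPDH ratio was not higher in OEC Lp than in OEC Ep on either type.

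Other cell type lists gave mixed results. Neuron markers fell for 3 of 8 genes (4 adjusted over the list alone; median -1.24), among them Nefl (at least 42.5-fold) and Uchl1 (at least 29.6-fold), with a camera adjusted p of 0.000344 (adjusted p = 0.372 with an estimated correlation). Oligodendrocyte markers fell for 3 of 8 genes, Sox10, Cnp (10.1-fold) and Ugt8 (at least 4.09-fold), and 4 adjusted over the list alone, with a median of -0.86 and a camera adjusted p of 0.00346 (adjusted p = 0.372 with an estimated correlation). Of those 8 genes 6 also stand on another list. Contractile genes fell for 2 of 14, Acta2 (at least 5.80-fold) and Cnn1 (at least 3.75-fold), and for 6 adjusted over the list alone (median -1.07, camera adjusted p = 0.000154; adjusted p = 0.498 with an estimated correlation). Astrocyte markers went both ways, with Gja1, a gap junction protein, up 13.1-fold and Aldoc down at least 6.05-fold. Of their 6 genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, and the list did not pass (median -0.98, camera adjusted p = 0.13). Fibroblast and meningeal markers did not pass either (median -0.58, camera adjusted p = 0.217), with 2 of 10 up and 2 down, or 2 and 4 adjusted over the list alone. Over all members of a type their median was -0.69 for 11 on U34A and 0.56 for 17 on RAE2.0, where 6 were at least 2-fold higher and 5 lower. The collagen gene Col3a1 (4.66-fold) and the transcription factor gene Prrx1 (at least 3.75-fold) rose, while Postn and Thy1 (at least 7.47-fold) fell. Endothelial markers, with 4 genes on both types, were not tested as a list. Their log2 folds were 1.15 for Flt1, 0.52 for Slco1a4, -0.14 for Icam2 and 0.04 for Egfl7, and their adjusted p-values ran from 0.485 to 0.963.

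Matrix proteases fell for 5 of 23 genes and rose for 1 (6 and 1 adjusted over the list alone; median -0.75, camera adjusted p = 0.000344; adjusted p = 0.372 with an estimated correlation). The plasminogen activators Plat (3.33-fold, log2 fold -1.74 ± 0.3, adjusted p = 0.0333) and Plau (at least 5.07-fold, adjusted p = 0.0374) fell, as did the cathepsins Ctsc (at least 20.9-fold) and Ctss, while Pcolce, an enhancer of collagen processing, rose 10.3-fold. Ctss is also on the macrophage list. Mmp2, Mmp9 and Mmp14, the matrix metalloproteinases looked up whatever their result, had log2 folds of -1.90, -2.49 and -0.30 that did not pass (adjusted p = 0.0868, 0.195 and 0.667). Protease inhibitors rose for 4 of 13 genes and fell for 0, or 4 and 2 adjusted over the list alone, although the list did not pass (median 0.79, camera adjusted p = 0.176). Timp2, an inhibitor of metalloproteinases, rose 5.11-fold (log2 fold 2.35 ± 0.306, adjusted p = 0.0162), Tfpi, the tissue factor pathway inhibitor, 8.11-fold, Serping1, the C1 inhibitor, 12.0-fold and Spint2, an inhibitor of serine proteases, 6.55-fold. Timp1 and Timp3 had log2 folds of 0.79 and -1.72 (adjusted p = 0.472 and 0.269). F2r had -3.11 ± 1.30 (adjusted p = 0.274). The values of Mmp2, Mmp9 and F2r are lower bounds in size.

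Integrins and adhesion molecules fell for 7 of 25 genes and rose for 1 (10 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 6.52e-05; adjusted p = 0.372 with an estimated correlation), with Itga1 down 25.5-fold and the cadherin Cdh2 at least 20.9-fold. Matrix components fell for 8 of 39 genes and rose for 4 (14 and 8 adjusted over the list alone; median -0.62, camera adjusted p = 0.029; adjusted p = 0.478 with an estimated correlation). Tnc, the matrix protein tenascin C, fell at least 16.6-fold and the proteoglycan Ncan at least 6.30-fold, Efemp1, a fibulin, rose 8.59-fold, and fibronectin, Fn1, had a log2 fold of 1.25 (adjusted p = 0.101). Among growth factors, Cntf, a survival factor for motor neurons, fell 9.28-fold, Tgfb3 at least 3.48-fold and Hbegf 3.84-fold, and Fgf1 rose at least 5.22-fold. That list had 2 genes up and 3 down of 35, or 2 and 5 adjusted over the list alone, and did not pass (median -0.13, camera adjusted p = 0.131). Bdnf and Gdnf had log2 folds of -0.65 and 0.28 (adjusted p = 0.528 and 0.746). Cytokines and complement had 1 gene up and 4 down of 30, or 2 and 4 adjusted over the list alone (median -0.03, camera adjusted p = 0.243). All 45 members on RAE2.0 had a median of -0.68, with 22 at least 2-fold lower and 3 higher, against 0.10 for 30 on U34A. Cx3cl1, the chemokine fractalkine, rose at least 10.7-fold, and Il33 fell at least 33.0-fold, Pf4 at least 12.6-fold and Ptgs1 at least 3.87-fold. In the axon guidance list Efna1, an ephrin, rose at least 6.53-fold, and no other gene of 15 passed, also when adjusted over the list alone. Its median of -0.12, mean of 0.13 and camera direction, down, differed in sign (adjusted p = 0.956). Of all 54 members of this list on RAE2.0, 13 were at least 2-fold higher and 8 lower, with no test.

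DNA replication genes had 0 of 21 genes passing, adjusted over all genes or adjusted over the list alone, with a positive median of 0.55 (camera adjusted p = 0.0337; adjusted p = 0.832 with an estimated correlation). Its lowest p-values were those of Tyms, thymidylate synthase (log2 fold 1.39, adjusted p = 0.101), and the helicase subunit Mcm7 (0.88, adjusted p = 0.269). Interferon and MHC genes likewise had 0 of 23 passing by either adjustment (median 0.67, camera adjusted p = 0.0372; adjusted p = 0.89 with an estimated correlation). The interferon-induced genes Rsad2 and Cxcl10 had log2 folds of 2.70, a lower bound, and 2.97 (adjusted p = 0.0776 and 0.0814). The median of this list was 1.81 on U34A and -0.20 on RAE2.0, and that of DNA replication 0.85 and 0.21. Over all 55 DNA replication members on RAE2.0 the median was 0.03, with 3 at least 2-fold higher and 4 lower. Genes induced by p53 fell for 2 of 13 and rose for 1 (5 and 1 adjusted over the list alone; median -1.12, camera adjusted p = 0.00458; adjusted p = 0.372 with an estimated correlation), with Btg1, an antiproliferative gene, down 5.06-fold, Igfbp3 down at least 5.23-fold and the epoxide hydrolase Ephx1 up 5.29-fold. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had -1.51 (adjusted p = 0.0529), a lower bound in size. Senescence genes and inhibitors of cyclin-dependent kinases had 1 up and 2 down of 15, or 2 and 3 adjusted over the list alone, with a median of 0.16, a mean of 0.00 and a camera direction that was down (adjusted p = 0.73); Igfbp5 fell at least 41.5-fold. Antioxidant genes had 3 up and 3 down of 38, or 4 and 6 adjusted over the list alone (median -0.01, camera adjusted p = 0.332), with Gpx3 down at least 27.7-fold, Sod3 down at least 22.3-fold and Gstm2 up 11.2-fold. Mitosis genes (0 of 23; median 0.37, adjusted p = 0.205), cholesterol synthesis genes (0 of 15; 0.44, adjusted p = 0.0623) and ribosomal proteins (0 of 32; 0.17, adjusted p = 0.339) did not pass and had no gene passing by either adjustment. Over all members of a type the mitosis median was 0.99 for 25 on U34A and -0.46 for 62 on RAE2.0. Glycolysis and hypoxia genes had Aldoc, on the astrocyte list too, as 1 gene down of 23 by both adjustments, and their median of 0.07, mean of -0.06 and camera direction, down, differed in sign (adjusted p = 0.811).

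Genes measured on RAE2.0 only are given as values with no test. Cldn11, a tight junction protein, had a signal 69.2-fold higher in OEC Lp, the transcription factor gene Foxp2 43.5-fold, Col8a2 34.2-fold and the small heat shock protein gene Hspb8 29.7-fold. Fbln2, a matrix fibulin, was 165-fold lower, the chemokine gene Ccl7 71.3-fold, Kctd12 46.3-fold and Fcer1g, a signalling subunit of myeloid Fc receptors, 44.2-fold. Cdkn2a, which codes for an inhibitor of cyclin-dependent kinases among its products, had signals of 528 in OEC Ep and 5948 in OEC Lp.

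Over all genes, limma called 192 of 3131 genes, 66 higher and 126 lower in OEC Lp, at an adjusted p under 0.05. All of them had the same sign and at least a 2-fold ratio on both array types, and 130 are lower bounds because a population was at the floor. Such agreement is built into the test, here and in the other comparisons, because its residual is the disagreement of the array types. The labels do not tell which RNA pool was on which array, so p-values may measure technical spread only. The count was 66 without a floor, 77 for genes above the floor on all arrays, 41 with the 4 arrays of these populations alone, 1 without the filter on dim probe sets and 0 without the replicate block of array type (193 at an unadjusted p under 0.05). None of the calls held without either OEC Ep array or either OEC Lp array, where the lone array left was assumed to vary like the other groups. Leaving out either TEG3 array gave the same fit as the 4 arrays alone, because a lone TEG3 array adds nothing to this comparison. The DNA replication list did not pass without the OEC Ep array of U34A (adjusted p = 0.351) or the OEC Lp array of U34A (0.964, with the direction turned), and the interferon list without these arrays (0.825 and 0.839, turned in the latter) or either TEG3 array (0.0546 and 0.0583). The matrix component list did not pass without either OEC Ep array (0.0974 and 0.0585) or the OEC Lp array of U34A (0.351), nor the p53 list without the OEC Ep or the OEC Lp array of RAE2.0 (0.0541 and 0.0689). With genes above the floor on all arrays the matrix protease list (0.423) and the matrix component list (0.309) did not pass, with the floor at the 60th percentile matrix components (0.108) and DNA replication (0.0947), and without the filter matrix components (0.0709) and interferon genes (0.296). DNA replication did not pass without the replicate block (0.0713), nor interferon genes with the 4 arrays alone (0.059).

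**Figure D2:**
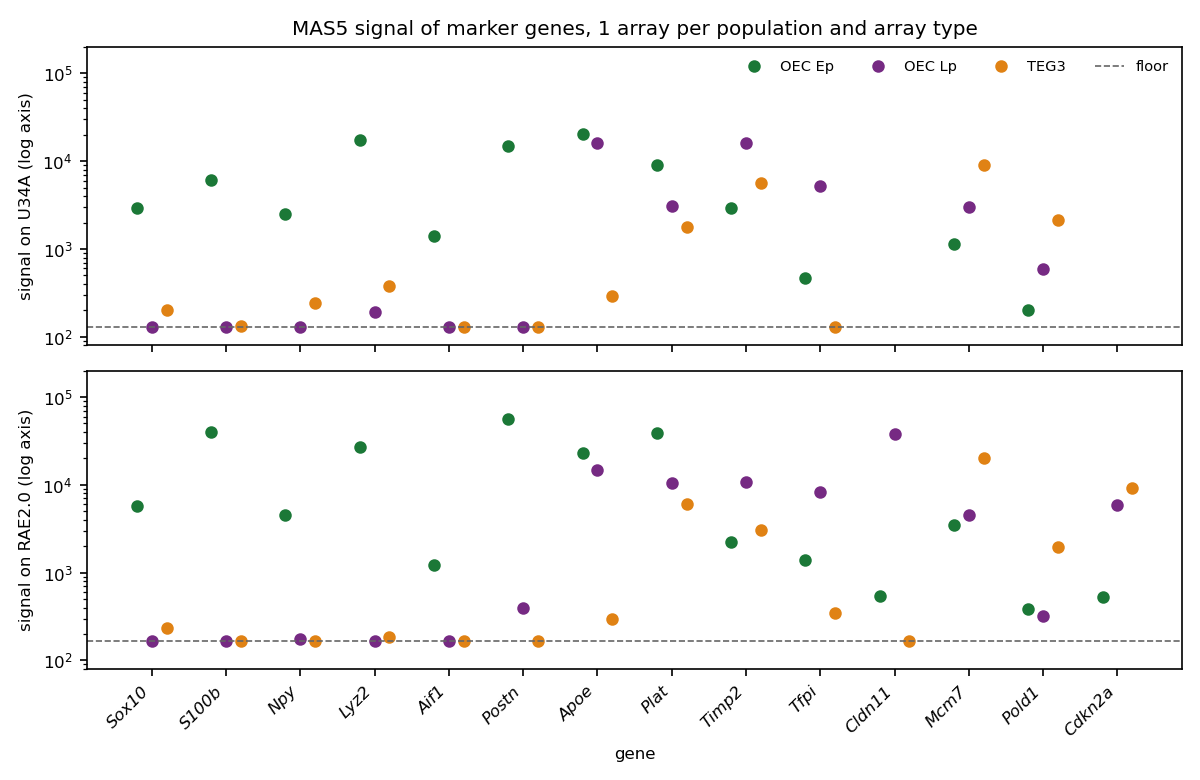
MAS5 signal (log axis) of 14 genes in OEC Ep, OEC Lp and TEG3 on U34A (top) and RAE2.0 (bottom), 1 array per point, with the floor as a dashed line; Cldn11 and Cdkn2a were measured on RAE2.0 only. Sox10, S100b, Npy, Lyz2, Aif1 and Postn are at 394 or less in OEC Lp and TEG3 on both types, Apoe is at 299 or less in TEG3 alone, and Tfpi is highest in OEC Lp.

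TEG3 was compared with OEC Ep to ask how the line made with large T antigen differs from the primary cells. Mcm7, a subunit of the replicative helicase, rose 6.72-fold (log2 fold 2.75 ± 0.361 SE, limma adjusted p = 0.0205), Pold1, the catalytic subunit of DNA polymerase delta, 7.31-fold (adjusted p = 0.0394), Ung, which removes uracil from DNA, at least 6.90-fold and Timeless, a protein of replication forks, at least 7.63-fold (log2 fold 2.93 ± 0.297, adjusted p = 0.0108). Klf4, a transcription factor, and Usp37, a deubiquitinase, rose at least 6.50-fold and 6.26-fold, and Myadm, a membrane protein, and Lox, an oxidase that crosslinks collagen, rose 6.47-fold and 5.89-fold. Apoe fell at least 73.0-fold (log2 fold -6.19 ± 0.297, adjusted p = 0.00274) and Serpine2, an inhibitor of thrombin and of plasminogen activators, 80.5-fold (-6.33 ± 0.774, adjusted p = 0.0173). Further large falls were those of Postn (at least 197-fold), Calcb (at least 134-fold), S100b (at least 106-fold), Nefm (at least 99.1-fold), Mgp, an inhibitor of calcification (at least 85.3-fold), Lyz2 (81.7-fold) and Scn7a (at least 77.0-fold).

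The 7 cell type lists tested were lower in TEG3 than in OEC Ep with the preset correlation (adjusted p = 0.372 to 0.612 with an estimated correlation). Of 8 endothelial markers on RAE2.0, not tested as a list, 1 was at least 2-fold higher and 0 lower. OEC and Schwann cell markers fell for 13 of 18 genes (16 adjusted over the list alone; 0 rose) with a median of -3.56, and Sox10 (18.9-fold), Npy (at least 16.7-fold), Gfra1 (at least 18.7-fold) and Vim (4.07-fold, adjusted p = 0.0296) were among them. Ngfr had a log2 fold of -4.02 ± 1.06 (adjusted p = 0.11), a lower bound in size, with -1.81 on U34A (signal 3621 in TEG3) and -6.22 on RAE2.0 (floor). Gfap was at the floor on RAE2.0 in TEG3. Microglia and macrophage markers fell for 7 of 12 genes (all 12 adjusted over the list alone; median -2.67), among them Cd48 (11.7-fold) and Aif1 (at least 8.93-fold). On RAE2.0, 21 of 23 were at least 2-fold lower. The camera adjusted p was 2.06e-15 for OEC and Schwann cell markers and 1.04e-10 for microglia and macrophage markers (adjusted p = 0.372 with an estimated correlation for both). Neuron markers (2 of 8 down, 4 adjusted over the list alone; median -1.15, camera adjusted p = 0.00236; adjusted p = 0.372 with an estimated correlation) included Nefl (at least 55.1-fold). Oligodendrocyte markers (2 of 8 down, 4 adjusted over the list alone; median -1.34, camera adjusted p = 0.0114; adjusted p = 0.372 with an estimated correlation) included Cnp (log2 fold -3.45). Fibroblast and meningeal markers fell for 3 of 10 genes (5 adjusted over the list alone; median -1.49, camera adjusted p = 0.00159; adjusted p = 0.372 with an estimated correlation), with Crabp2, a carrier of retinoic acid, down 67.8-fold and Thy1 at least 7.47-fold, and Col1a2 at a log2 fold of -5.07, a lower bound in size, that did not pass (adjusted p = 0.058). Over all 17 members on RAE2.0 their median was -0.07, with 3 at least 2-fold higher and 6 lower. Astrocyte markers fell for 1 of 6 genes, S100b (3 adjusted over the list alone; median -1.15, camera adjusted p = 0.0244; adjusted p = 0.41 with an estimated correlation), and contractile genes for 1 of 14, Cnn1 (3 adjusted over the list alone; median -0.90, camera adjusted p = 0.00458; adjusted p = 0.612 with an estimated correlation). The GAPDH ratio in TEG3 was below that in OEC Ep on U34A (1.54 against 1.96) and the same on RAE2.0 (1.02).

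Of 21 DNA replication genes 4 rose, Mcm7, Pola2 (4.55-fold), Prim1 (5.35-fold) and Pold1, and 17 adjusted over the list alone, with 0 down and a median of 1.79. The camera adjusted p was 1.76e-11 (adjusted p = 0.41 with an estimated correlation), and on RAE2.0 alone 51 of 55 members were at least 2-fold higher. Mitosis genes had 0 of 23 passing limma over all genes but 12 up adjusted over the list alone (median 1.34, camera adjusted p = 3.83e-07; adjusted p = 0.52 with an estimated correlation). Ccne1, the cyclin of the entry into S phase, had a log2 fold of 1.64 (adjusted p = 0.0797), and 43 of 62 members were at least 2-fold higher on RAE2.0. Cholesterol synthesis genes had 0 of 15 passing by either adjustment, with a positive median of 0.69 (camera adjusted p = 0.0172; adjusted p = 0.797 with an estimated correlation). Genes induced by p53 fell for 2 of 13, Btg1 (3.81-fold) and Igfbp3 (at least 4.02-fold), and for 4 adjusted over the list alone (median -0.83, camera adjusted p = 0.0127; adjusted p = 0.372 with an estimated correlation). Senescence genes and inhibitors of cyclin-dependent kinases had 3 of 15 down, or 4 up and 5 down adjusted over the list alone, with Igfbp5 down at least 50.6-fold and the cyclin gene Ccnd2 at least 13.5-fold. The median of this list was 0.18 against a mean of -0.45 and a camera direction that was down (adjusted p = 0.74).

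Matrix components, proteases, inhibitors and adhesion molecules were lower in TEG3 as lists. Matrix components fell for 8 of 39 genes and rose for 1 (18 and 4 adjusted over the list alone; median -0.88, camera adjusted p = 2.18e-05; adjusted p = 0.372 with an estimated correlation), with Tnc down at least 17.5-fold, Spp1, the secreted protein osteopontin, at least 54.0-fold and Ncan at least 5.46-fold. Matrix proteases fell for 4 of 23 (9 down and 1 up adjusted over the list alone; median -1.07, camera adjusted p = 1.6e-05; adjusted p = 0.372 with an estimated correlation). These were Plat (5.73-fold, log2 fold -2.52 ± 0.3, adjusted p = 0.0165), Plau (at least 6.76-fold), Ctss (at least 20.9-fold) and Ctsc (6.08-fold). Integrins and adhesion molecules fell for 6 of 25 (9 adjusted over the list alone; median -0.84, camera adjusted p = 6.28e-05; adjusted p = 0.372 with an estimated correlation), with Itga1 down 11.2-fold, L1cam at least 12.7-fold and Alcam 6.19-fold. Protease inhibitors fell for 2 of 13, Serpine2 and Tfpi (at least 3.88-fold), and for 6 adjusted over the list alone (median -0.84, camera adjusted p = 0.0156; adjusted p = 0.373 with an estimated correlation). Log2 folds that did not pass were -1.35 for Mmp2, -2.49 for Mmp9, -0.65 for Mmp14, 0.04 for Timp1, 0.69 for Timp2, -2.42 for Timp3 and 0.72 for F2r, with adjusted p-values from 0.131 to 0.981. Fn1 had -0.17 (adjusted p = 0.801), Bdnf 0.09 (0.951) and Gdnf 0.34 (0.674). The values of Mmp2, Mmp9, Timp3 and Fn1 are lower bounds in size, and Timp1 and Bdnf had opposite signs on the array types.

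The other lists did not pass in this comparison. Growth factors had 2 of 35 down, Ptn, the heparin-binding factor pleiotrophin (17.1-fold), and Cntf (5.36-fold), also adjusted over the list alone (median -0.20, camera adjusted p = 0.111). Cytokines and complement had 2 of 30 down, Il33 and Pf4, and 6 adjusted over the list alone (median -0.52, camera adjusted p = 0.11). The types opposed each other, with a median of 0.33 for 30 members on U34A and of -1.17 for 45 on RAE2.0, where 23 were at least 2-fold lower and 2 higher. Antioxidant genes had 4 of 38 down, among them Nqo1 (at least 10.9-fold), and 6 down and 1 up adjusted over the list alone (median -0.08, camera adjusted p = 0.141). Efna1 was the 1 axon guidance gene of 15 that rose by both adjustments (median 0.11, camera adjusted p = 0.983). Of all 54 members of that list on RAE2.0, 7 were at least 2-fold higher and 11 lower, with no test. Interferon and MHC genes (0 of 23; median 0.26, adjusted p = 0.43), glycolysis and hypoxia genes (0 of 23; 0.19, adjusted p = 0.565) and ribosomal proteins (0 of 32; 0.25, adjusted p = 0.105) had no gene passing by either adjustment. On RAE2.0 only, Cdkn2a was 17.5-fold higher in TEG3, the laminin gene Lama5 15.7-fold, Cdca7 13.6-fold and Dtl, a factor of replication licensing, 12.0-fold, while Rassf4 was 65.8-fold lower, Fcer1g 65.3-fold, Afap1l2 63.4-fold and Plekhb1 33.5-fold.

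In this comparison limma called 136 genes, 20 higher and 116 lower in TEG3. All had the same sign and at least a 2-fold ratio on both array types, and 87 are lower bounds. The count was 86 for genes above the floor on all arrays, 11 without a floor, 1 without the filter, 0 with the 4 arrays of these populations alone (623 at an unadjusted p under 0.05) and 0 without the replicate block (172). None of the calls held without any 1 of the 6 arrays. Without an OEC Ep or TEG3 array, the lone array left was assumed to vary like the other groups. Leaving out an OEC Lp array gave the same fit as the 4 arrays alone. Among the lists, the adjusted p was above the threshold without the OEC Ep array of RAE2.0 for contractile (0.0541), astrocyte (0.0861), oligodendrocyte (0.0582), p53 (0.222) and protease inhibitor genes (0.0669), and without the OEC Ep array of U34A for cholesterol synthesis (0.223). It was so without the TEG3 array of RAE2.0 for astrocyte (0.0968), cholesterol (0.16), p53 (0.0595) and inhibitor genes (0.0519), and without that of U34A for contractile genes (0.0546). Astrocyte markers did not pass without a floor (0.0614) or without the filter (0.077), neuron markers without the filter (0.0709), oligodendrocyte markers without the filter (0.0648) or with the floor at the 60th percentile (0.107), and inhibitors with that floor (0.0524).

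TEG3 was set against OEC Lp to ask how the populations adapted to long culture differ from each other. Apoe was lower in TEG3, by at least 52.4-fold (log2 fold -5.71 ± 0.297 SE, limma adjusted p = 0.00836). Tfpi, which blocks the start of coagulation, fell at least 31.4-fold (-4.97 ± 0.358, adjusted p = 0.0232) and Serping1 at least 38.7-fold (-5.28 ± 0.542, adjusted p = 0.0333). Tnnt2 (at least 54.7-fold), Efemp1 (at least 37.9-fold), Omd (at least 24.1-fold), Tmem47, a junction protein (at least 22.3-fold), and the integrin Itgb4 (at least 21.7-fold) fell as well. The 6 genes that rose were Ltbp1, which binds latent TGF-beta (at least 27.0-fold, log2 fold 4.75 ± 0.458, adjusted p = 0.0296), Uchl1, a ubiquitin hydrolase of neurons (at least 17.2-fold), Bcat1, which breaks down branched-chain amino acids (8.40-fold), Basp1, a growth cone protein (6.39-fold), the adenosine receptor Adora2b (at least 5.75-fold) and Fabp5, a carrier of fatty acids (4.90-fold).

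Among the lists, DNA replication genes were higher in TEG3 than in OEC Lp (median 1.35, camera adjusted p = 4.63e-11; adjusted p = 0.41 with an estimated correlation). None of the 21 passed limma over all genes, with Mcm7 at a log2 fold of 1.87 (adjusted p = 0.0829) and Pold1 at 2.21 (adjusted p = 0.112), and 13 rose adjusted over the list alone. On RAE2.0, 49 of 55 were at least 2-fold higher. Mitosis genes had 0 of 23 passing by either adjustment, with a median of 0.95 (camera adjusted p = 9.37e-07; adjusted p = 0.532 with an estimated correlation) and 48 of 62 at least 2-fold higher on RAE2.0. The array types differed in size: with genes on both types, the mitosis median was 0.30 on U34A and 1.63 on RAE2.0. That of DNA replication was 0.86 on U34A and 1.90 on RAE2.0. Protease inhibitors were lower, with Tfpi and Serping1 down of 13 genes and 8 down and 1 up adjusted over the list alone (median -1.37, camera adjusted p = 9.58e-06; adjusted p = 0.372 with an estimated correlation). Cst3, the cysteine protease inhibitor cystatin C, had a log2 fold of -2.50 (adjusted p = 0.0729) and Timp2 -1.66 (adjusted p = 0.0749). Fibroblast and meningeal markers were lower (median -0.93, camera adjusted p = 0.00704; adjusted p = 0.372 with an estimated correlation) with 0 of 10 passing over all genes and 5 down adjusted over the list alone. Crabp2, Col1a2 and Col3a1 had log2 folds of -4.99, -5.58 and -2.02 (adjusted p = 0.0508, 0.0745 and 0.0607), that of Col1a2 as a lower bound in size. Matrix components had 2 of 39 down, Efemp1 and Loxl1, a collagen crosslinking oxidase (8.43-fold), and 9 down and 1 up adjusted over the list alone (median -0.33, camera adjusted p = 0.0279; adjusted p = 0.478 with an estimated correlation). Over all members of a type their median was 0 for 41 on U34A and -0.61 for 67 on RAE2.0.

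Markers of OECs and Schwann cells did not pass between these populations. Apoe was the 1 gene of 18 that fell over all genes, and 2 fell adjusted over the list alone. The median of 0.01, mean of -0.35 and camera direction, down, differed in sign (adjusted p = 0.636). Sox10 had a log2 fold of 0.56 (adjusted p = 0.518), S100b 0.02, Npy 0.43, Ngfr 0.25 and Vim -1.78 (adjusted p = 0.0647). Signals of S100b were near or at the floor in both populations, those of Sox10 and Npy likewise in OEC Lp and at most 243 in TEG3. Those of Ngfr were at the floor on RAE2.0 but 2569 in OEC Lp and 3621 in TEG3 on U34A. These folds do not show that the populations are alike. Microglia and macrophage markers had 1 of 12 down, Cd48 (6.03-fold), by both adjustments, with a median of 0.00 (camera adjusted p = 0.856). Neuron markers had 1 of 8 up, Uchl1, by both adjustments (median 0.03, camera adjusted p = 0.692). Integrins and adhesion molecules had 2 of 25 down, Itgb4 and Alcam (6.90-fold), or 2 down and 1 up adjusted over the list alone, with a median of 0.11, a mean of -0.06 and a camera direction that was up (adjusted p = 0.712). Growth factors had Fgf1 down at least 5.40-fold of 35, or 3 down and 2 up adjusted over the list alone, with a median of 0.02, a mean of -0.13 and a camera direction that was up (adjusted p = 0.96). Cx3cl1 was the 1 of 30 cytokine genes that fell (at least 8.51-fold), and 2 fell adjusted over the list alone (median 0.00, camera adjusted p = 0.674). Plat, Plau, Mmp2 and Mmp14 had log2 folds of -0.78, -0.41, 0.55 and -0.34 with adjusted p-values from 0.305 to 0.724, and matrix proteases had 0 of 23 passing by either adjustment (median -0.34, camera adjusted p = 0.415). Timp1, Timp3, F2r, Bdnf, Gdnf and Fn1 had -0.75, -0.70, 3.83, 0.74, 0.05 and -1.43 with adjusted p-values from 0.121 to 0.977, and Mmp9 and Thy1 were at the floor in both populations. The values of Timp3, F2r and Fn1 are lower bounds in size, and Bdnf and Gdnf had opposite signs on the array types.

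The remaining 11 lists did not pass, with camera adjusted p-values of 0.148 for interferon and MHC, 0.211 for glycolysis and hypoxia, 0.43 for contractile, 0.565 for cholesterol synthesis, p53 and ribosomal genes, 0.601 for oligodendrocyte and antioxidant, 0.674 for astrocyte, 0.747 for axon guidance and 0.796 for senescence genes, and 0 genes called in any of them. Adjusted over the list alone, 1 contractile and 1 astrocyte gene rose, and 2 astrocyte, 1 p53, 2 senescence and 5 antioxidant genes fell. Of all 54 axon guidance members on RAE2.0, 3 were at least 2-fold higher and 13 lower, with no test. The senescence list had a median of 0.24 and a mean of -0.46 with a camera direction that was down, and the oligodendrocyte list a median of -0.06 and a mean of 0.05 with a direction that was up. On RAE2.0 only, Fbln2 was 30.2-fold higher in TEG3, Htra1, a secreted protease, 22.4-fold, Cxcl1, a chemokine, 17.6-fold and Armcx4 14.2-fold. Colec12, a scavenger receptor, was 61.5-fold lower, Prrx2, a homeobox gene, 39.3-fold, Ifitm1 36.7-fold and Zbtb7c 25.9-fold.

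Between TEG3 and OEC Lp, limma called 38 genes, 6 higher and 32 lower in TEG3, all with the same sign and at least a 2-fold ratio on both array types, 21 of them as lower bounds. The count was 77 with median scaling, which held all 38, and 0 without a floor (437 at an unadjusted p under 0.05), without the filter (469), with the 4 arrays of these populations alone (375) and without the replicate block (110). None of the calls held without any 1 of the 6 arrays. Without an OEC Lp or TEG3 array, the lone array left was assumed to vary like the other groups. Leaving out an OEC Ep array gave the same fit as the 4 arrays alone. Among the lists, fibroblast markers did not pass without the TEG3 array of RAE2.0 (adjusted p = 0.0583), nor matrix components without that array (0.271), the OEC Lp array of RAE2.0 (0.38) or the OEC Ep array of RAE2.0 (0.0534). Matrix components did not pass either without the filter (0.106), with the brightest probe set of each gene (0.0692) or with the 4 arrays alone (0.0502).

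**Figure D3:**
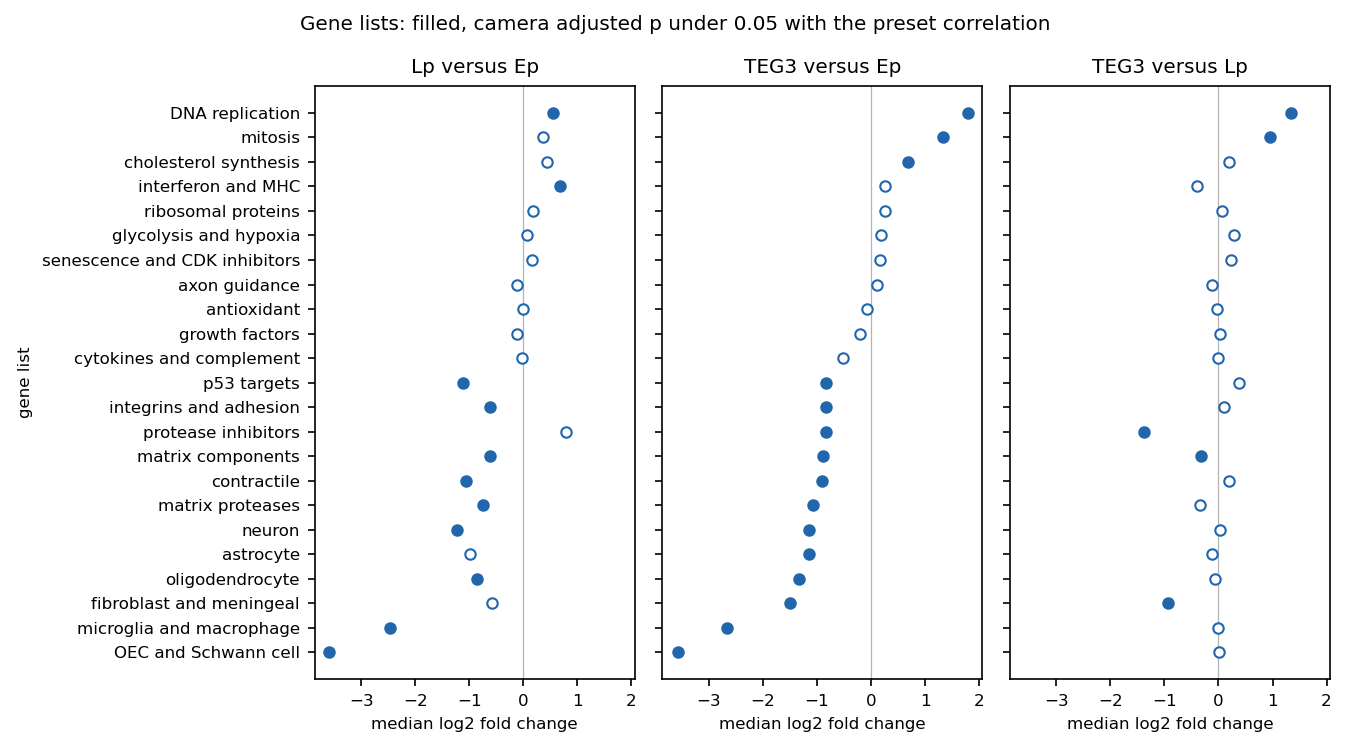
Median log2 fold (x axis) of 23 gene lists in the 3 pairwise comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation. OEC and Schwann cell markers and microglia and macrophage markers are lowest in both comparisons with OEC Ep (medians -3.60 and -2.48 in OEC Lp, -3.56 and -2.67 in TEG3), and DNA replication is highest in TEG3.

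The contrast of OEC Lp with the mean of the other populations follows the study's division of these cells by their capacity to promote the regrowth of axons, with OEC Lp on the poor side. Genes higher in OEC Lp included the protease inhibitors Serping1 (at least 21.5-fold, log2 fold 4.43 ± 0.469 SE, limma adjusted p = 0.0189) and Timp2 (4.02-fold, 2.01 ± 0.265, adjusted p = 0.0258). Tnnt2 (at least 56.9-fold, 5.83 ± 0.434, adjusted p = 0.0184), Omd (at least 23.3-fold), Efemp1 (at least 18.1-fold), Akr1c14, a steroid reductase (at least 16.9-fold), and Itgb4 (at least 16.5-fold) were higher too. Lower in OEC Lp were Ltbp1 (at least 23.5-fold, -4.55 ± 0.396, adjusted p = 0.0189), Uchl1 (at least 22.6-fold), Tubb2b (at least 17.0-fold), Rcn3, a calcium-binding protein of the endoplasmic reticulum (14.4-fold), Lyz2 (at least 13.4-fold) and Bcat1 (10.8-fold). Sox10 was lower by at least 6.40-fold. The folds of Sox10 and Lyz2 come mostly from the level in OEC Ep. Sox10 was at the floor in OEC Lp and low in TEG3. Signals of Lyz2 were 17260 in OEC Ep, 192 in OEC Lp and 378 in TEG3 on U34A. On RAE2.0 they were 27310, 168 and 187. S100b and Npy passed the p threshold (adjusted p = 0.0385 and 0.0317) but not the rule that both pairwise differences have the same sign on both types. Plat, Plau, Mmp2, Mmp9, Mmp14 and F2r had log2 folds of -0.48, -0.96, -1.23, -1.24, 0.02 and -3.47 that did not pass, with adjusted p-values from 0.201 to 0.98. Timp1, Timp3, Bdnf, Gdnf, Ngfr, Fn1, Vim and Thy1 had 0.77, -0.51, -0.69, 0.11, -2.26, 1.34, 0.77 and -1.45, with adjusted p-values from 0.0759 to 0.894. The values of F2r and Fn1 are lower bounds in size, and those of Plau, Mmp2, Mmp9, Timp3, Bdnf, Gdnf, Ngfr and Thy1 rest in part on populations at the floor.

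Protease inhibitors rose for 4 of 13 genes and fell for 0 in this contrast (5 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 0.00163; adjusted p = 0.372 with an estimated correlation). Matrix proteases had 1 of 23 down, or 2 adjusted over the list alone, and did not pass (median -0.28, camera adjusted p = 0.0709). Microglia and macrophage markers had 1 of 12 down, Lyz2, and 7 adjusted over the list alone (median -1.34, camera adjusted p = 9.3e-06; adjusted p = 0.372 with an estimated correlation). Of the 18 OEC and Schwann cell markers Sox10 fell, and 13 fell and 2 rose adjusted over the list alone (median -1.68, camera adjusted p = 1.75e-06; adjusted p = 0.41 with an estimated correlation); with genes above the floor on all arrays the mean log2 fold of this list was 0.19 (adjusted p = 0.838). Between TEG3 and OEC Lp the medians of these marker lists were 0.00 and 0.01, so their values in this contrast come from the level in OEC Ep. Contractile, integrin, neuron, oligodendrocyte, p53 and DNA replication genes were lower and interferon genes higher as lists, with camera adjusted p-values from 0.00346 to 0.029 and adjusted p = 0.372 to 0.878 with an estimated correlation. Of these 7 lists only DNA replication passed between TEG3 and OEC Lp. The DNA replication median was 0.55 in OEC Lp against OEC Ep, and in TEG3 it was 1.79 against OEC Ep and 1.35 against OEC Lp. The list was therefore not lower in OEC Lp than in OEC Ep, and its value in this contrast comes from the level in TEG3. In the contrast with the mean, DNA replication had 0 of 21 genes and interferon 0 of 23 passing by either adjustment. Over all members of a type, the DNA replication median was 0.06 on U34A and -0.94 on RAE2.0, and the interferon median 1.13 and -0.05. Without the OEC Lp array of RAE2.0 the contractile (0.519), p53 (0.28) and DNA replication (0.853, turned) lists did not pass, and without that of U34A the interferon list (0.488, turned) did not. Without the OEC Ep array of RAE2.0 it was the DNA replication (0.0541), integrin (0.08), oligodendrocyte (0.0527) and p53 (0.0899) lists, and interferon genes did not pass without the OEC Ep (0.441) or TEG3 (0.109) array of U34A or without the filter (0.148), nor DNA replication without the TEG3 array of RAE2.0 (0.13). The p53 list did not pass with the floor at the 60th percentile (0.0524), with genes above the floor on all arrays (0.0546) or without the replicate block (0.0739).

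In all, limma called 99 of 3131 genes, 70 higher and 29 lower in OEC Lp, of which 60 are lower bounds, out of 122 that passed before the rule on direction, and all 99 had the same sign on both types. The count was 48 for genes above the floor on all arrays, 0 without a floor (486 at an unadjusted p under 0.05), 0 without the filter (538) and 0 without the replicate block (161). It was 0 without any 1 of the 6 arrays (372 to 450 at an unadjusted p under 0.05), with the lone array assumed to vary like the other groups.

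The contrast of OEC Ep with the mean of OEC Lp and TEG3 asks which genes set the short-term culture apart from both long-term populations. Postn (at least 159-fold, log2 fold 7.32 ± 0.39 SE, limma adjusted p = 0.00232), Calcb (at least 134-fold, 7.06 ± 0.404, adjusted p = 0.00232), S100b (at least 106-fold), Lyz2 (at least 99.4-fold), Nefm (at least 99.1-fold) and Scn7a (at least 77.4-fold) were higher in OEC Ep. Sox10 (at least 22.9-fold), Npy (at least 19.4-fold), Thy1 (at least 7.47-fold) and the plasminogen activators Plat (4.37-fold, 2.13 ± 0.26, adjusted p = 0.0139) and Plau (at least 5.85-fold) were higher as well. Lower in OEC Ep were Gjb2 (9.27-fold), Myadm (8.93-fold), Pcolce (8.84-fold), Masp1 (at least 8.68-fold), Igfbp6 (at least 8.11-fold), Clu (log2 fold -2.91, adjusted p = 0.0189) and Timp2 (2.87-fold, -1.52 ± 0.265, adjusted p = 0.0335). Ngfr had a log2 fold of 4.14 ± 0.921 that did not pass (adjusted p = 0.0686). Mmp2, Mmp9, Mmp14, Timp1, Timp3, F2r, Bdnf, Gdnf, Fn1 and Vim had 1.62, 2.49, 0.48, -0.42, 2.07, 1.20, 0.28, -0.31, -0.54 and 1.14, with adjusted p-values from 0.0758 to 0.737. The values of Ngfr, Mmp2, Mmp9 and Timp3 are lower bounds in size, and Timp1, F2r and Bdnf had opposite signs on the array types.

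OEC and Schwann cell markers were higher in OEC Ep for 13 of 18 genes (17 adjusted over the list alone; median 3.52, camera adjusted p = 1.98e-16), microglia and macrophage markers for 7 of 12 (all 12 adjusted over the list alone; median 2.39, camera adjusted p = 1.23e-11) and matrix proteases for 5 of 23 with 1 lower (11 and 1 adjusted over the list alone; median 1.12, camera adjusted p = 1.35e-05). Each had adjusted p = 0.372 with an estimated correlation. DNA replication genes were lower, with 2 of 21 down and 13 adjusted over the list alone (median -1.19, camera adjusted p = 3.83e-07; adjusted p = 0.488 with an estimated correlation). Mitosis and cholesterol synthesis genes were lower too, and integrin, contractile, neuron, matrix component, oligodendrocyte, p53, fibroblast and astrocyte genes higher, with camera adjusted p-values from 1.54e-05 to 0.0372 and adjusted p = 0.372 to 0.797 with an estimated correlation. Mitosis had 0 of 23 genes and cholesterol synthesis 0 of 15 passing by either adjustment. The mitosis, cholesterol, fibroblast and astrocyte lists passed between TEG3 and OEC Ep but not between OEC Lp and OEC Ep. DNA replication passed in both comparisons with OEC Ep, but its median was 1.79 in TEG3 and 0.55 in OEC Lp. In OEC Lp against OEC Ep 0 of its 21 genes passed by either adjustment, and all 55 members on RAE2.0 had a median of 0.03. Without the OEC Ep array of U34A the mitosis (0.0504), cholesterol (0.351) and fibroblast (0.0745) lists did not pass, and without that of RAE2.0 the p53 (0.0887) and astrocyte (0.0726) lists did not. Cholesterol genes did not pass without the OEC Lp array of U34A (0.16) or the TEG3 array of RAE2.0 (0.0771), nor astrocyte markers without either TEG3 array (0.0638 and 0.0785), without a floor (0.092) or without the filter (0.0919), nor fibroblast markers without the filter (0.11).

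Over all genes, limma called 178 of 3131, 146 higher and 32 lower in OEC Ep, 123 of them as lower bounds, out of 181 that passed before the rule on direction, and all 178 had the same sign on both types. The count was 104 for genes above the floor on all arrays, 70 without a floor, 6 without the replicate block and 1 without the filter. It was 31 without the TEG3 array of U34A, 16 without that of RAE2.0 and 0 without any 1 of the OEC Ep or OEC Lp arrays (393 to 581 at an unadjusted p under 0.05), with the lone array assumed to vary like the other groups.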

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

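All alternatives were planned, and the residual spread without the filter was looked at only after its count was seen. The 249 named results of single genes that follow include uncalled ones, which had no call to lose. The shares that stayed the same are therefore higher than among called results alone. Without the filter 167 of the 249 lost the call. Over 249 named results of single genes, 1877 of 2520 values under alternatives other than leave-one-out kept direction and side of the threshold, 592 lost the call, 40 gained one and 11 reversed; in leave-one-out 521 of 1494 were the same, 937 lost the call and 36 reversed. Over 55 called list results 834 of 1000 were the same, 161 lost the call and 5 reversed. Counts of called genes are given in the order OEC Lp against OEC Ep, TEG3 against OEC Ep, TEG3 against OEC Lp, OEC Lp against the mean of the others, OEC Ep against the mean of the others, with 192, 136, 38, 99 and 178 by limma in the analysis reported. They were 66, 11, 0, 0 and 70 without a floor (514, 568, 437, 486 and 566 at an unadjusted p under 0.05); 1, 1, 0, 0 and 1 without the filter (605, 644, 469, 538 and 638), where 538 of 4582 genes had a residual SD under 0.01 and the prior SD was 0.0509 against 0.36; and 0, 0, 0, 0 and 6 without the replicate block (193, 172, 110, 161 and 197). With genes above the floor on all arrays, where 2093 genes were tested, they were 77, 86, 48 and 104, with TEG3 against OEC Lp within 1.5 times. The 4 arrays compared alone gave 41, 0 and 0 (529, 623 and 375), and median scaling gave 77 for TEG3 against OEC Lp. For a pairwise comparison, leaving out 1 array of the third population is the same fit as the 4 arrays alone. Leave-one-out gave 0 to 41, 0, 0, 0 and 0 to 31, with fewer arrays and the lone array assumed to vary like the other groups, and 45 to 58 called list tests. Called list tests, 55 in the analysis reported, were 29 of 69 with the arrays compared alone, 15 with fry and 0 of 115 with an estimated correlation (7 at an unadjusted p under 0.05). The mean r of the array types moved with no alternative. Probe sets changed at least 2-fold, in the order of the 3 pairwise comparisons, were 7188, 7370 and 6625 on RAE2.0 and 2451 and 2215 on U34A (TEG3 against OEC Ep and against OEC Lp) without a floor; 2677, 2910 and 2311 on RAE2.0 and 907, 926 and 708 on U34A with the floor at the 60th percentile; 2952 on RAE2.0 (OEC Lp against OEC Ep) and 897, 1019 and 822 on U34A above the floor on all arrays; and 1336, 1203 and 936 on RAE2.0 and 454, 417 and 310 on U34A at 4-fold. Among lists, the mean log2 fold of OEC Lp against OEC Ep reversed without the OEC Lp array of U34A for DNA replication (leave-one-out range -0.038 to 1.001) and interferon genes (-0.041 to 1.633). For OEC Lp against the mean it reversed for DNA replication without the OEC Lp array of RAE2.0 (-0.949 to 0.09), for interferon genes without that of U34A (-0.158 to 1.516) and for OEC and Schwann cell markers above the floor on all arrays (0.193). Reversed single genes were uncalled throughout, and their leave-one-out ranges of log2 fold follow. For OEC Lp against OEC Ep these were Egfl7 (-0.091 to 0.163, with -0.027 under quantile normalization, -0.005 under median scaling and -0.259 with the brightest probe set), Icam2 (-0.37 to 0.089, with 1.573 without a floor), Flt1 (-0.241 to 2.537), Gdnf (-0.168 to 0.734) and Slco1a4 (-0.183 to 1.221). For TEG3 against OEC Ep they were Bdnf (-0.686 to 0.865, with -0.155 without a floor), Timp1 (-0.735 to 0.825, with -0.063 under median scaling), F2r (-0.775 to 2.208), Fn1 (-0.42 to 0.07) and Gdnf (-0.141 to 0.815). For TEG3 against OEC Lp they were Gdnf (-0.424 to 0.532, with -0.006 without a floor), Npy (-0.151 to 1.021, with -0.971 without a floor), Bdnf (-0.039 to 1.512), Ngfr (-0.978 to 1.473), Plau (-0.996 to 0.167) and S100b (-0.584 to 0.617). For OEC Lp against the mean they were Mmp14 (-0.112 to 0.151, with -0.038 under median scaling and -0.003 with the brightest probe set), Gdnf (-0.337 to 0.566) and Timp3 (-1.178 to 0.152). For OEC Ep against the mean they were Bdnf (-0.155 to 0.713, with -0.01 with the floor at the 60th percentile), F2r (-0.295 to 2.687) and Timp1 (-1.199 to 0.361). Apart from fewer arrays, fewer genes and the spread without the filter, the cause was not tested. Median scaling moved the median log2 fold of all genes in OEC Lp against OEC Ep from 0.11 to 0.01. Signals near the background limit the folds: 130, 87, 21, 60 and 123 of the called genes are lower bounds.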

Other observations

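The genes of this paragraph are given by their signals on RAE2.0 and were chosen after their values were seen. Mki67, a protein of dividing nuclei, had signals of 4428 in OEC Ep, 2896 in OEC Lp and 10500 in TEG3, and Ccna2, a cyclin of S phase and G2, had 3572, 1758 and 5132. Cdkn2a, whose products restrain the cell cycle, had 528, 5948 and 9257, so it was highest in TEG3, as was Mki67. The mitosis list in OEC Lp against OEC Ep, with genes on both types, had a median of 1.01 on U34A and -0.32 on RAE2.0. Some transcription factors of the head mesenchyme and meninges were above the floor in OEC Lp: Tbx18 had 168, 2511 and 369, Foxc1 168, 2118 and 200, and Zic4 168, 1313 and 168. Another, Foxc2, differed little, with 186.5, 207.7 and 178.4. The meningeal markers Aldh1a2 (380, 168 and 168) and Slc13a3 (2190, 168 and 168) went the other way.

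All tests of explanations in this part were chosen only after the result was seen.

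OEC and Schwann cell markers were lower in OEC Lp and TEG3 than in OEC Ep; 7 of the 18 genes are on another list too. The floor or the scaling was argued against, since the mean log2 fold nearest 0 over the alternatives was -1.359, and so was poorer RNA, since the highest GAPDH 3' to 5' ratio relative to OEC Ep was 1.002. For TEG3, described as a clonal line, the markers did not decide on overgrowth by fibroblasts. Of 5 abundant markers 60% (Postn, Crabp2 and Col1a2) were at least 10-fold lower on both types, and 0 of 10 were at least 2-fold higher. The 5 were chosen for their level in OEC Ep, so their fall does not show that fibroblasts were absent. The other abundant markers did not go that far, Col3a1 (log2 ratios 0.23 on U34A and 0.16 on RAE2.0) and Col1a1 (-0.35 and -1.41). Of all 17 markers on RAE2.0, 3 were at least 2-fold higher and 6 lower. Overgrowth stayed open in OEC Lp with 20% and 2 of 10, and with 6 of the 17 at least 2-fold higher and 5 lower; this criterion was the last of 3 tried, after shares no higher than OEC Ep (40% in OEC Lp, 70% in TEG3) had decided nothing and shares near the floor were dropped, and 8 of the 10 are on another list. Meningeal cells in OEC Lp stayed open too: of 8 markers on RAE2.0 on no earlier list, 4 were at least 2-fold higher and 2 lower (median log2 ratio 0.838, percentile 99.4 of random lists), which met a criterion first set at 50% only at its boundary and was then read as undecided, and these 8 are part of a wider set of 13 computed first (median 1.687). The idea came from named genes such as Cldn11, Gjb2 and Omd, the 23 markers were written after that, the most abundant of the 8, Slc13a3, went the other way (2190 in OEC Ep, floor in OEC Lp), and loss of the markers by the OECs themselves over many doublings was not tested and stays open, as does donor age for TEG3.

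Microglia and macrophage markers were lower in OEC Lp and TEG3 than in OEC Ep; 1 of the 12 genes is on another list. Fewer myeloid cells than in OEC Ep and lower expression by the OECs themselves could not be told apart: 91.3% of 23 markers on RAE2.0 (21) were at least 2-fold lower in both, which either would give. The most abundant were Lyz2 (27306 in OEC Ep, 168 in OEC Lp, 187 in TEG3), Fcer1g (13972, 316 and 214) and Cd48 (8681, 3453 and 553), and the stated purity over 90% leaves room for some other cells. The scaling and the level of the floor were argued against, since the mean log2 fold nearest 0 over the alternatives that could be run was -1.957. The setting with genes above the floor on all arrays could not be run for this list. Too few of its genes were above the floor in all populations, so the part played by the floor was not fully tested.

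Some lists differed between the array types, for example interferon and MHC genes in OEC Lp against OEC Ep with medians of 1.81 on U34A and -0.20 on RAE2.0. Of 69 list tests 26 (37.7%) lay outside the central 95% of random lists, where 3.45 would be expected of independent tests. This does not decide whether probes that differ gene by gene are the cause. The random lists were matched on signal but not on size of change, and the tests share genes and arrays. Lists that fell on both types count among the 26, such as OEC and Schwann cell markers in OEC Lp against OEC Ep (medians -2.59 on U34A and -4.03 on RAE2.0). RNA of different cultures on the arrays of a population could give such shifts, and 8 of 12 tests of the interferon, mitosis, DNA replication and cytokine lists lay outside. The labels name no pool for each array, so this cannot be told apart from the probes or from other differences between the hybridisations. No biological explanation was tested for this pattern.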
